A study of Mus musculus with 2 samples.

How the data were processed

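RNA was measured in 2 libraries of mouse hindbrain, the part of the embryonic brain that forms the medulla, pons and cerebellum, taken at embryonic day 12.5 (e12.5). Per the labels, each library came from its own pool of embryos of both sexes of the B6NCrl strain, 120 embryos for replicate 1 and 88 embryos for replicate 2. Both are biological replicates of 1 group, so no contrast between conditions exists, and every p-value given compares 2 libraries. Per the labels' protocols, RNA longer than 200 nt was extracted with the mirVana method, libraries started from 10 ng of total RNA, external ERCC spike-in RNAs were added, and the manual of a SMARTer ultra-low input kit is among the linked protocols. Whether the libraries keep strand is not given in the sources used here, so values of overlapping and antisense genes are uncertain.

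The authors deposited, for each library, 1 table of genes and 1 table of transcripts on the mouse assembly mm10. The accompanying notes name the GENCODE M4 annotation and say that the values derive from an alignment to the transcriptome. The aligner and the quantifier are not given in the sources used here. The deposited expected counts are estimated numbers of fragments per gene that need not be whole, since fragments matching several genes are divided among them. The deposited TPM values, per the file headers, are length-normalised transcript abundances with 1 fixed total shared by all genes and spike-ins of a library. A posterior mean TPM with lower and upper bounds was deposited beside it, and the level of that interval is not stated, so the bounds are not used here. The deposited FPKM values, per the file headers, are fragment counts scaled by transcript length and library size. The transcript tables hold, per the file headers, the share of each gene's expression in each transcript as a percent. The effective lengths in the files equal the transcript length minus 99 nt for all transcripts above the shortest.

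Each gene table holds 69691 entries, of which 43346 are Ensembl genes, 96 are ERCC spike-ins and 26248 are numbered entries that name no gene. The numbered entries held 0.000107% and 0.000114% of the expected counts of replicates 1 and 2 and stayed out of every test. Gene names and coordinates came from GENCODE M21 on the same assembly, matched on the Ensembl identifier without its version. Of the Ensembl genes, 42462 were matched and 884 were not, and the unmatched genes held 0.315% and 0.306% of the TPM. All 393 genes of the fixed lists were matched to 1 identifier each. Genes with near-identical copies, such as the globin pairs, clustered histones, 7SL RNA genes and nuclear copies of mitochondrial genes, depend on how the authors divided shared fragments and are uncertain.

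The libraries held 31633169 expected counts in replicate 1 and 29766460 in replicate 2. At an effective length of 1 kb, 3 counts correspond to 0.158 TPM in replicate 1 and 0.171 TPM in replicate 2, taken as the limit that a count of 0 allows. These floors, and the intervals of shares, cover counting error only, since amplified fragments without molecular identifiers are not independent molecules.

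The gene lists (40 lists), the rule for named genes and the main tests were fixed before the data were examined. Added later were the contrasts of dorsal with ventral factors and of neuron with progenitor genes, the adjustments over a list alone, the sums over Hox paralogue groups, the rho within single Hox clusters, and every test of a candidate explanation in the closing section with the margin of 1 standard error. From each list the 4 members of highest mean TPM are named, with the lowest where it shows the range. Also named are all Hox genes at a mean of 10 TPM or more, every sex-linked gene, the 10 nuclear protein-coding genes of highest mean TPM, the 8 genes with the largest log2 ratio in each direction between libraries among those at a mean of 5 TPM or more with an adjusted p below 0.05, the isoform genes whose dominant transcript differed, and the 6 isoform genes of highest TPM. Some genes that the rule names are not reported here. Genes named outside the rule are said to be so. A gene was called detected at 1 TPM or more in both libraries. Lists were summarised by the median TPM of their members in each library, and contrasts of lists by the difference of median log2(TPM+1) within each library.

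For tests, expected counts were rounded to whole numbers. Genes with 10 or more counts summed over the libraries were scaled by TMM in edgeR 4.0.16 (R 4.3.3), which gave factors of 0.99968 and 1.0003, and a common dispersion was estimated with an intercept-only design. Each gene was compared by a two-sided exact binomial test (scipy 1.17.1), which allows for counting error only, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The edgeR exact test with the common dispersion added was the alternative, with the limit that its dispersion came from the same 2 libraries. Folds are ratios of TPM, while tests use counts, so the pair can part where the effective length of a gene differs between libraries. The shift of a list is the median log2 ratio of TPM+1, replicate 2 over replicate 1, and it understates changes of genes near 1 TPM. It was set against 10000 random lists of protein-coding genes of the same size matched on mean TPM, with the central 95% as the range. Members of a list are not independent of each other, so that range is narrower than the chance spread of a list of co-expressed genes.

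The procedures were tested on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed. At a simulated coefficient of variation of 0.1 between libraries, the exact binomial test called 89.6% of genes changed 1.5-fold, 98.5% at 2-fold and all at 4-fold, and it also called 31.8% of 19249 genes tested that had not changed. With the dispersion added, the edgeR exact test called 8.96%, 47.8% and all of these, and 0.0105% of unchanged genes. The list shift was run without simulated counts, on 200 lists of 10 measured genes drawn at random, and 4% fell outside the range of random lists. Both kinds of list came from the same genes, so a low rate was built in. It says nothing about lists of co-expressed genes.

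Alternatives tried were FPKM, the posterior mean TPM, TPM recomputed without spike-ins, mitochondrially encoded genes and entries that are not Ensembl genes, other pseudocounts and minimum levels, DESeq2 1.42.0 size factors, unscaled totals, no minimum count and each library alone. A smooth trend (lowess, statsmodels 0.14.6) of the log2 ratio over effective length and then over GC content was removed in an alternative chosen after the data were seen. Plots were drawn with matplotlib 3.10.9.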

Results

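The data are RNA profiles of the hindbrain of e12.5 mouse embryos, measured in 2 libraries started from total RNA of separate pools of 120 and 88 embryos. The labels give 1 tissue at 1 age, so the design yields the expression profile of this tissue with its replicate error. The libraries held 31633169 expected counts in replicate 1 and 29766460 in replicate 2. Values are mean ± SD over both libraries (n = 2) unless given per library, and coordinates are on mm10.

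Hox genes, which encode homeodomain factors that mark position along the head-to-tail axis, were expressed mainly in paralogue groups 2 to 6, with little of the most anterior group and almost none at the posterior end. Summed TPM of group 1 was 6.47 and 5.07 in replicates 1 and 2, against 91.5 and 118 for group 2. Hoxb5 (chromosome 11, 96303336 to 96306121) was the highest at 81.2 ± 29.1 TPM (SD, n = 2). It was followed by Hoxd3 at 61.9 ± 7.52, Hoxa5 at 55.3 ± 16.6, Hoxb2 at 53.6 ± 8.66 and Hoxa2 at 51.3 ± 10.3 TPM. Hoxc4 was at 38.2 ± 14.1, Hoxc5 at 22.7 ± 9.37, Hoxb3 at 13.9 ± 2.18 and Hoxa3 at 13.4 ± 3.20 TPM. The annotated spans of Hoxd3, Hoxa3 and Hoxc5 contain those of Hoxd4, Hoxa4 and Hoxc6. The division of fragments among such genes, and so between paralogue groups, may be uncertain. Of the 15 genes of paralogue groups 1 to 5, 14 reached 1 TPM in both libraries, the exception being Hoxb1 at 1.83 TPM in replicate 1 and 0.66 TPM in replicate 2. Of the 8 genes of groups 6 to 8, 5 reached 1 TPM, led by Hoxb6 at 50.6 ± 2.93 and Hoxa6 at 15.9 ± 0.905 TPM. None of the 16 genes of groups 9 to 13 did, and the highest single value among them was 0.38 TPM, from 33 counts over all 16 genes in replicate 1 and 20 counts in replicate 2.

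The median log2(TPM+1) of paralogue groups 1 to 5 exceeded that of groups 6 to 13 by 3.87 ± 0.27 (SD, n = 2), with 3.68 in replicate 1 and 4.06 in replicate 2, so the difference was far larger than its spread. Across the 39 Hox genes, Spearman's rho of paralogue number with expression was -0.765 in replicate 1 and -0.777 in replicate 2, a description across genes that are not independent. Within single clusters it was weakest in cluster b, at -0.394 and -0.491. With a pseudocount of 0.1 in place of 1, the difference was 6.91.

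**Figure D1:**
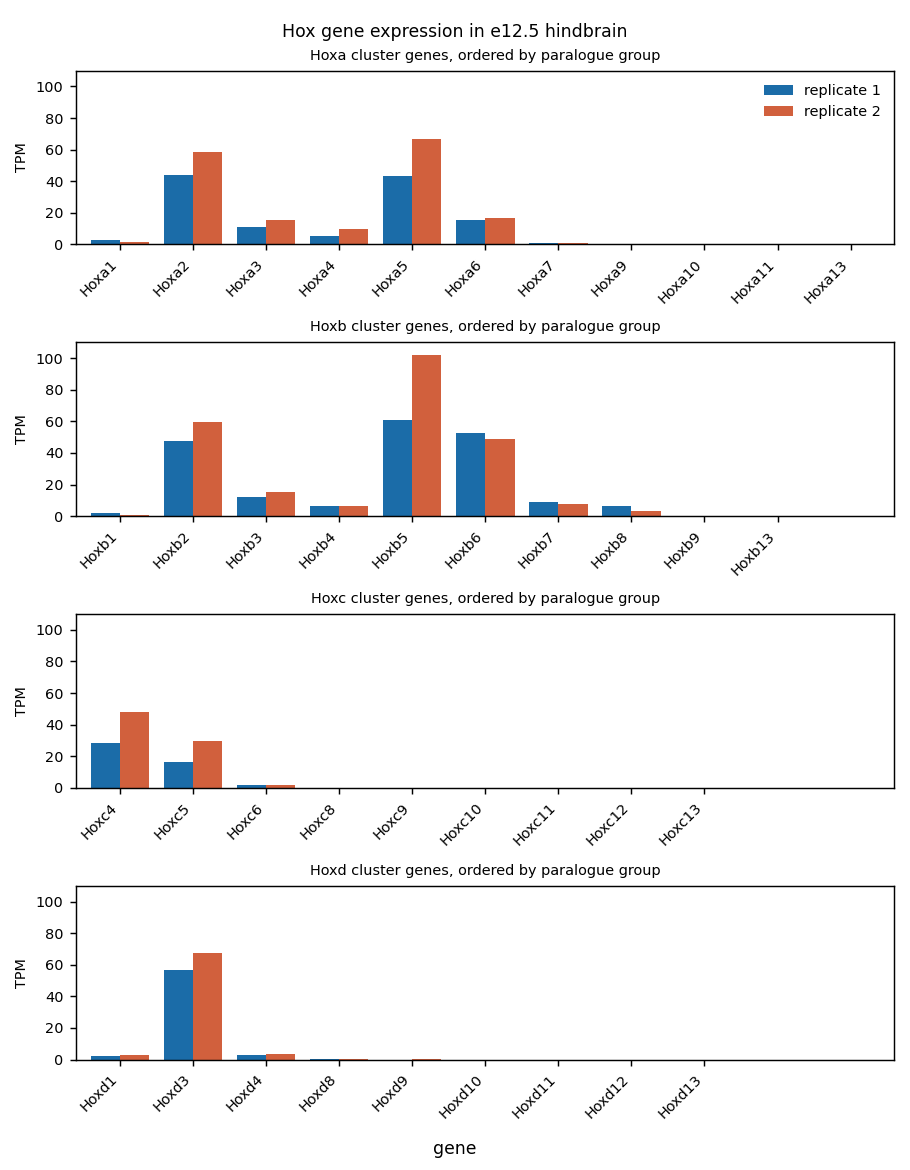
Expression of each Hox gene in TPM (vertical axis, linear from 0) in replicate 1 (blue) and replicate 2 (orange), with a panel for each cluster and genes ordered by paralogue group. Hoxb5 stands highest at 60.6 and 102 TPM, and no gene of groups 9 to 13 exceeds 0.38 TPM.

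Transcription factors of hindbrain patterning were far above those of more anterior brain regions. The median of the 14 hindbrain patterning factors was 42.7 ± 2.60 TPM, against 6.78 ± 0.304 TPM for 12 midbrain and isthmus factors and 0.787 ± 0.202 TPM for 16 forebrain factors. The TALE homeodomain genes Meis1 (154 ± 16.7 TPM), Meis2 (115 ± 13.1) and Pbx3 (87.8 ± 1.97), which encode partners of Hox proteins, led the hindbrain list with Irx2 (53.3 ± 3.15), and Egr2, a rhombomere gene of earlier stages, was lowest at 1.06 ± 0.233. Among midbrain and isthmus factors Pax8 (26.8 ± 6.53), Otx2 (14.1 ± 2.32), Pax2 (13.7 ± 1.90) and Barhl1 (7.66 ± 0.431) were highest. Among forebrain factors Lhx2 (25.2 ± 0.311), Neurod6 (16.4 ± 2.59), Dlx5 (11.9 ± 4.65) and Dlx1 (7.48 ± 0.948) were highest, and 6 of the 16 reached 1 TPM in both libraries. The difference of median log2(TPM+1) was 2.49 ± 0.03 between hindbrain and midbrain lists and 4.63 ± 0.06 between hindbrain and forebrain lists (SD, n = 2). Both were many times their spread between libraries.

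Dorsal progenitor domain factors had a median of 9.02 ± 1.97 TPM and ventral ones 3.36 ± 0.311 TPM, a log2 difference of 1.17 ± 0.16. Msx1 (86.7 ± 12.3 TPM), Msx2 (50.9 ± 2.52) and Olig3 (35.6 ± 3.26) were among the highest dorsally, and Dbx1 (19.8 ± 7.27), Nkx6-1 (16.0 ± 0.460), Nkx6-2 (14.9 ± 0.636) and the floor plate signal Shh (4.41 ± 0.636) led ventrally. The rhombic lip and cerebellar glutamatergic lineage, at a median of 14.3 ± 0.361 TPM, was led by Mab21l1 (81.0 ± 4.92), Neurod1 (22.6 ± 2.80), Lhx9 (19.6 ± 1.44) and Pax6 (15.3 ± 1.17). The cerebellar GABAergic lineage, at 15.9 ± 1.76 TPM, was led by Pcp4 (86.0 ± 9.98), Lhx1 (54.6 ± 1.75), Lhx5 (54.3 ± 2.12) and Foxp2 (37.6 ± 1.53). Hindbrain interneuron factors had a median of 12.9 ± 1.11 TPM, with Pou4f1 (48.6 ± 7.80), Gata3 (45.4 ± 8.90), Foxp2 and Tlx3 (25.8 ± 2.10) highest.

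Genes of differentiated neurons were the highest of the neural lists. Postmitotic neuron genes had a median of 281 ± 16.3 TPM, with the neuronal tubulin Tubb3 at 849 ± 9.38, Ina at 489.7 ± 27.5, Nefl at 419.7 ± 26.3 and Stmn3 at 409 ± 4.21. Proliferation genes were at 112 ± 6.70 TPM, led by Cdk1 (173 ± 6.23), Rrm2 (169 ± 4.92), Top2a (159 ± 3.56) and Ccnb1 (148 ± 9.55). Neural stem and progenitor genes were at 71.9 ± 6.91 TPM, led by the radial glial genes Fabp7 (1227 ± 108) and Vim (849 ± 32.5), the Notch target Hes5 (252 ± 22.6) and Sox9 (159.5 ± 0.962). Neurogenic commitment genes were at 41.6 ± 1.22 TPM, with Hes6 (235 ± 18.8), Gadd45g (139 ± 11.3), Btg2 (79.3 ± 8.85) and the Notch ligand Dll1 (51.6 ± 2.57) highest. Neuron genes exceeded progenitor genes by 1.97 ± 0.22 in log2 (SD, n = 2). Oligodendrocyte lineage genes were at 11.2 ± 0.00354 TPM. That near match of the 2 medians is no measure of error, since 2 of 10 members were called lower in replicate 2 with dispersion added. The list was led by Pdgfra (41.2 ± 5.28), Cldn11 (25.4 ± 0.212), Cnp (23.6 ± 0.255) and Mbp (13.8 ± 1.89). Pdgfra is also held by the meningeal and mesenchymal list. Mobp, a gene of mature myelin, was at 0.04 TPM in each library. Astrocyte genes were at 6.47 ± 0.658 TPM, led by the gap junction gene Gja1 (142 ± 16.0), Aldoc (16.4 and 13.6 TPM in replicates 1 and 2), Slc1a2 (13.2 ± 1.08) and Aldh1l1 (13.1 ± 3.70), and Gfap was lowest at 0.04 and 0.09 TPM, below the value of 3 counts at 1 kb.

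Medians of the transmitter lists lay below those of the neuron, proliferation, progenitor and neurogenic commitment lists. The glutamatergic and the GABA and glycine lists stood above the oligodendrocyte and astrocyte lists. Among glutamatergic genes, the vesicular transporter Slc17a6 was at 33.5 ± 2.65, Slc17a8 at 1.88 ± 0.332 and Slc17a7 at 0.720 ± 0.0849. GABA and glycine genes were at 16.4 ± 1.20 TPM, with the glutamate decarboxylases Gad2 (43.5 ± 4.18) and Gad1 (19.2 ± 0.912) and the transporter Slc6a9 (13.6 ± 3.32) among the highest. Cholinergic and motor neuron genes were at 8.66 ± 1.53 TPM, with Isl1 (36.4 ± 1.04), Prph (23.2 ± 6.73) and Isl2 (14.9 ± 1.96) among the highest. Serotonergic genes were at 4.47 ± 0.863 TPM, with Slc18a2 (14.1 ± 0.283), Ddc (8.41 ± 2.26), the serotonergic factor Fev (5.96 ± 0.431) and Maob (4.88 ± 1.77) highest. Tph2, which encodes the enzyme of the first step of serotonin synthesis in the brain, was lowest at 2.71 ± 0.601. Noradrenergic genes were at 3.12 ± 0.410 TPM, led by Tfap2b (71.3 ± 3.66), with Th (12.2 ± 0.0707) and Phox2a (3.12 ± 0.410) also among the highest. Dopaminergic genes were at 2.94 ± 0.265 TPM, led by Nr4a2 (20.0 ± 3.72), Th, Foxa2 (3.83 ± 0.537) and Pitx3 (1.77 ± 1.46), and the dopamine transporter Slc6a3 was at 0.05 and 0.03 TPM.

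**Figure D2:**
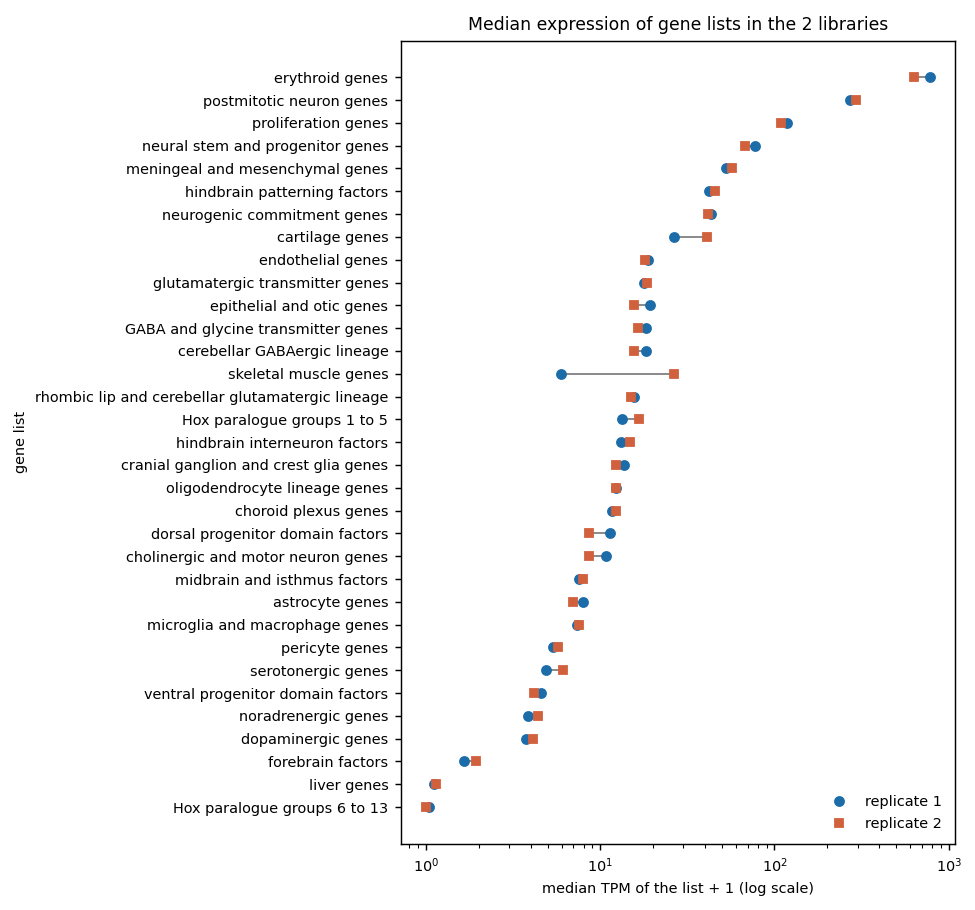
Median TPM plus 1 (horizontal axis, log scale) of 33 gene lists in replicate 1 (blue circles) and replicate 2 (orange squares), each pair joined by a line. Postmitotic neuron genes stand at 269 and 293 TPM, and the skeletal muscle list has the widest gap, from 4.96 to 25.4 TPM.

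RNA of blood, vessels and mesenchyme was present beside neural RNA. Erythroid genes had the highest median of any cell type list, 708 ± 108 TPM, with the embryonic globin Hbb-y at 7255 ± 1264, Hba-a2 at 5863 ± 822, Hba-a1 at 2697 ± 436 and Hba-x at 1500.1 ± 284 TPM, where the values of the near-identical pair Hba-a1 and Hba-a2 are uncertain. Meningeal and mesenchymal genes were at 53.9 ± 2.95 TPM, led by the collagens Col3a1 (525 ± 109.7), Col1a1 (484 ± 98.5) and Col1a2 (353 ± 51.4) and by Lum (132 ± 21.1). Cartilage genes were at 32.7 ± 10.1 TPM, led by Col2a1 (387 ± 14.8), Col9a1 (84.2 ± 2.93), Col11a1 (52.8 ± 13.7) and Hapln1 (12.6 ± 6.48). Endothelial genes were at 17.4 ± 0.438 TPM, with Cldn5 (26.5 ± 2.73), Esam (26.1 ± 0.438), Kdr (25.6 ± 0.269) and Pecam1 (17.8 ± 0.537) highest. Epithelial and otic genes were at 16.5 ± 2.55 TPM, led by the otoconial gene Oc90 (177 ± 99.4), Epcam (24.7 ± 11.7), Krt18 (20.8 ± 6.14) and Krt8 (20.5 ± 6.42). The skeletal muscle list was at 4.96 TPM in replicate 1 and 25.4 TPM in replicate 2, so its level rests on the library chosen.

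Cranial ganglion and crest glia genes were at 11.9 ± 1.01 TPM, with Pou4f1 and Prph among the highest. Choroid plexus genes were at 11.0 ± 0.506 TPM, with transthyretin (Ttr) at 354 ± 42.8, Kcne2 at 17.6 ± 4.43, Otx2 at 14.1 ± 2.32 and Clic6 at 11.6 ± 1.07. Microglia and macrophage genes were at 6.41 ± 0.127 TPM, led by the complement genes C1qb (27.0 ± 1.70) and C1qa (13.2 ± 1.75), Csf1r (11.2 ± 0.106) and Aif1 (6.42 ± 0.113). Pericyte genes were at 4.53 ± 0.226 TPM, led by Pdgfrb (30.7 ± 1.22), Notch3 (19.02 ± 0.0283), Cspg4 (4.50 ± 0.693) and Rgs5 (4.48 ± 0.339). Liver genes were at 0.125 ± 0.0212 TPM, where Ttr is shared with the choroid plexus list, Apoa2 was at 2.80 ± 0.841, Apoa1 at 1.44 ± 0.0495 and Afp at 0.125 ± 0.0212, and albumin (Alb) had no counts.

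All 10 imprinted, 10 heterochronic and 6 sex-linked genes reached 1 TPM in both libraries. Imprinted genes had a median of 187 ± 5.50 TPM, with Cdkn1c at 698 ± 104, Mest at 695 ± 89.7, Meg3 at 668 ± 13.1 and Igf2 at 275 ± 21.2. Heterochronic genes were at 48.7 ± 2.25 TPM, led by Sox11 (479.9 ± 11.7), Sox4 (221 ± 18.7), Mycn (69.6 and 66.1 in replicates 1 and 2) and Igf2bp1 (58.3 ± 1.54), and the early stage gene Lin28a was lowest at 1.12 ± 0.0141. Transcripts of both sexes were present in each pool, with Xist at 24.1 and 19.7 TPM and Tsix at 7.85 and 7.64 TPM in replicates 1 and 2. The Y-linked genes were at 39.0 and 31.1 (Eif2s3y), 14.8 and 17.5 (Ddx3y), 13.3 and 15.2 (Uty), and 11.7 and 12.8 TPM (Kdm5d). Xist and Tsix overlap on opposite strands, so their values are uncertain. Immediate early and heat shock genes were at 2.38 ± 0.495 TPM, led by Dnajb1 (64.4 ± 4.81), Jun (63.6 ± 8.39), Ier2 (51.6 ± 0.990) and Junb (5.36 ± 0.849). Hypoxia and glycolysis genes were at 22.0 ± 0.594 TPM, led by Ldha (707 ± 31.4), Pgk1 (226 ± 3.46), Slc2a1 (95.7 and 84.3 in replicates 1 and 2) and Bnip3 (75.4 ± 0.00707).

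At 1 TPM or more in both libraries, 15381 of 43346 Ensembl genes were detected, 13520 of them protein-coding, 356 antisense and 275 lincRNA genes. The highest nuclear protein-coding gene was the tubulin Tuba1a (chromosome 15, 98949837 to 98953703) at 8626 ± 32.2 TPM. Hbb-y and Hba-a2 came next, followed by Actb at 5657 ± 8.12, Tmsb10 at 4819 ± 297, Ftl1 at 4806 ± 244, Tmsb4x at 4781 ± 184, Stmn1 at 3796 ± 82.7, Ppia at 3384 ± 34.6 and Nnat at 3141 ± 13.1. The 10 highest Ensembl genes of any type took 6.63% ± 0.652 of TPM. Globin genes took 1.91% ± 0.308, cytoplasmic ribosomal protein genes 4.15% ± 0.367, replication-dependent histone genes 0.372% ± 0.0596 and snRNA 0.0218% ± 0.00459 of TPM (SD, n = 2). Whether the library method captures all types of RNA equally was not tested, so these shares may not reflect the tissue. Mitochondrially encoded genes took 2.32% ± 0.251 of TPM and 1.15% (95% Wilson interval 1.15% to 1.16%) and 0.943% (0.940% to 0.947%) of the expected counts of replicates 1 and 2, led by mt-Atp8 (5080.2 ± 5.66 TPM), mt-Atp6 (4752 ± 730.5), mt-Cytb (1896 ± 126) and mt-Nd1 (1726 ± 48.0).

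Most genes used the same dominant transcript in both pools. Of 8395 genes with several annotated transcripts and 5 TPM or more in both libraries, 7759 (92.4%, 95% Wilson interval 91.8% to 93.0%) had the same highest transcript, and the median difference in its share was 3.07 percentage points. Among the 20 isoform genes, whose median was 151 ± 3.93 TPM, Nrcam differed, with Nrcam-201 at 48.9% and 54.3% and Nrcam-202 at 51.1% and 45.7% in replicates 1 and 2, so the order of its 2 transcripts was not resolved. The pyruvate kinase gene Pkm (1106 ± 51.7 TPM) was 75.5% ± 0.375 Pkm-201 and 24.5% ± 0.375 Pkm-202, and Cdc42 (552 ± 11.9) was 80.2% ± 0.198 Cdc42-202. The leading shares were 38.6% ± 0.311 for Tpm1-213, 39.4% ± 3.78 for Map2-201 and 52.0% ± 0.290 for Clta-206. Dcx-203 held 50.1% ± 4.04 of Dcx (195 ± 24.9 TPM).

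The pools matched closely across genes. Over 16642 genes at 1 TPM or more in at least 1 library, Pearson's r of log2(TPM+1) was 0.983 and Spearman's rho 0.986, across genes that are not independent. The SD of the log2 ratio fell from 0.64 at 1 to 5 TPM to 0.14 at 100 TPM and above, and the common coefficient of variation between libraries was 9.02%. In the simulated counts the same estimate read 0.0749 for a simulated 0 and 0.123 for a simulated 0.1. The 200 changed genes of the simulation entered that estimate, so it cannot show whether 9.02% is too high. The spread was beyond sampling noise, with a chi-square of 8.27 per degree of freedom over 19209 genes, which argues only against 1 library deposited 2 times. They were kept as 2 replicates because the labels name separate pools. ERCC spike-ins took 3.41% (95% Wilson interval 3.40% to 3.41%) and 4.36% (4.35% to 4.37%) of expected counts in replicates 1 and 2, and 8.39% and 10.9% of TPM. Of the 96 spike-ins, 80 were detected in both, with r = 0.994 of log2(TPM+0.01). Among 47 with 50 or more counts in each library the median log2 ratio was 0.35 with an SD of 0.15.

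Genes of contractile muscle stood out between the pools. The exact binomial test called 3846 of 19209 genes, 2024 higher and 1822 lower in replicate 2. With the between-library dispersion added, the edgeR exact test called 301, of which 181 were higher and 120 lower. Sarcomere genes were 6 of the 8 largest rises in replicate 2, with Ttn (chromosome 2, 76703980 to 76982547) at 1.98 and 15.3 TPM (log2 ratio 2.45), Tnnc2 at 4.02 and 25.3 (2.39), Myh3 at 3.53 and 21.1 (2.29), Mybph at 1.92 and 12.9 (2.25), Neb at 2.56 and 15.7 (2.23) and Myl1 at 8.83 and 42.9 (2.16). The adjusted p from the edgeR exact test was 3.97e-31 for Myh3 and 3.18e-25 for Ttn. An Ensembl gene without a name in M21, ENSMUSG00000103508.1, went from 1.98 to 13.1 TPM. The other large ratios lay mostly in pseudogenes and copies whose counts are uncertain. Gm14539 had 0 and 20.8 counts, Gm17122 78.0 and 0, and Hist1h2ah 66.2 and 0 in replicates 1 and 2. Gm15027 and Gm14536 each had 15.6 and 1.56 counts, and neither passed once dispersion was added (adjusted p 0.0914, edgeR exact test). Gm6344 was at 9.27 and 0.74 TPM, Gm3362 at 8.49 and 1.67, Gm10146 at 102 and 33.5, and the protein-coding gene Tom1 at 10.4 and 2.82 TPM.

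Muscle and skeletal tissue genes were higher, and the epithelial and otic list and blood genes lower, in replicate 2. The 8 skeletal muscle genes had a median log2 ratio of 1.89 (3.70-fold), against -0.11 to 0.15 for random lists. All 8 rose by the exact binomial test, 8 when adjusted over the list alone and 8 with dispersion added. They included the actins Actc1 (27.4 to 112 TPM) and Acta1 (8.06 to 38.0 TPM) and the myogenic factor Myog (6.38 to 29.6 TPM), with Myf5 the lowest (0.53 to 2.30 TPM). The cartilage list shifted by 0.77, and 6 of its 6 genes rose, 6 when adjusted over the list alone and 3 with dispersion added (Hapln1, Acan and Matn1, the last chosen after its values were seen). Its summed TPM was 1.13-fold, since the most abundant member, Col2a1, was at 376 and 397 TPM. The epithelial and otic list shifted by -0.60 (0.660-fold), 6 of 8 fell and 0 rose. Adjusted over the list alone, 7 fell and 1 rose, and with dispersion added 3 fell, namely Oc90 (247 to 107 TPM), Epcam (33.0 to 16.4) and Otog (1.17 to 0.38). The erythroid list shifted by -0.30 (0.812-fold), or -0.17 (0.889-fold) with the length and GC trends removed, and 9 of 10 fell, 9 when adjusted over the list alone and 0 with dispersion added. Of the 13 mitochondrially encoded protein genes, whose median shift was -0.22, 11 fell, 11 when adjusted over the list alone and 0 with dispersion added.

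Hox genes of paralogue groups 1 to 5 shifted by 0.33 (1.25-fold). Of 15, 10 rose and 1 fell by the exact binomial test, or 10 and 2 when adjusted over the list alone, and 4 rose with dispersion added (Hoxa4, Hoxb5, Hoxc4 and Hoxc5, of which Hoxa4 was chosen after its values were seen). Summed TPM in replicate 2 was 0.784-fold, 1.29-fold, 1.23-fold, 1.59-fold and 1.65-fold that in replicate 1 for paralogue groups 1 to 5 in turn, and 0.956-fold, 0.909-fold and 0.581-fold for groups 6, 7 and 8. Meningeal and mesenchymal genes shifted by 0.28 with 8 of 10 called higher, cranial ganglion and crest glia genes by 0.27 with 5 higher and 2 lower, and choroid plexus genes by 0.21 with 4 higher. Adjusted over the list alone these were 8, then 5 and 2, then 5, and with dispersion added the single call was a fall of Sox10 (15.4 to 9.60 TPM), chosen after its values were seen. The median TPM of the cranial ganglion list itself went down, from 12.65 to 11.22, although its median ratio was positive. Neural stem and progenitor genes shifted by -0.11 with 7 of 14 lower (7 adjusted over the list alone), and proliferation genes by -0.07 with 8 of 12 lower (10 adjusted over the list alone). Postmitotic neuron genes shifted by 0.09 with 8 higher and 2 lower (8 and 2 adjusted over the list alone). No member of these 3 lists was called with dispersion added.

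In all, 21 of the 40 lists lay outside the central 95% of random lists, 13 higher and 8 lower. Lists of independent genes would give 2 by chance. These lists hold co-expressed genes and some share members, so their own chance count is not known. The remaining higher lists were forebrain factors (0.20), cholinergic and motor neuron genes (0.19), midbrain and isthmus factors (0.17), isoform genes (0.13), imprinted genes (0.12) and hindbrain interneuron factors (0.12). In the cholinergic and isoform lists the median TPM itself went down in replicate 2, from 9.75 to 7.58 and from 154 to 148, although their median ratios were positive. The remaining lower lists were ventral progenitor domain factors (-0.14), dorsal progenitor domain factors (-0.13) and neurogenic commitment genes (-0.09). Calls in the interneuron list were split, with 3 of 14 higher and 3 lower, or 4 and 3 adjusted over the list alone. They were also mixed in the forebrain (6 higher, 2 lower), cholinergic (6 and 3) and isoform (10 and 2) lists. Adjusted over the list alone the forebrain calls were 6 and 3, and the cholinergic and isoform calls were the same. With dispersion added, 2 forebrain factors were called higher and 1 lower, and no cholinergic, isoform or imprinted gene was called. In the ventral list the calls ran against the median, since 2 of 12 genes were called higher and 0 lower, and the same 2 and 0 adjusted over the list alone. Endothelial (0.03), pericyte (0.11), microglia and macrophage (0.10), hindbrain patterning (0.03) and sex-linked genes (0.04) lay inside the range. These shifts compare 2 pools and carry no replicate of their own.

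**Figure D3:**
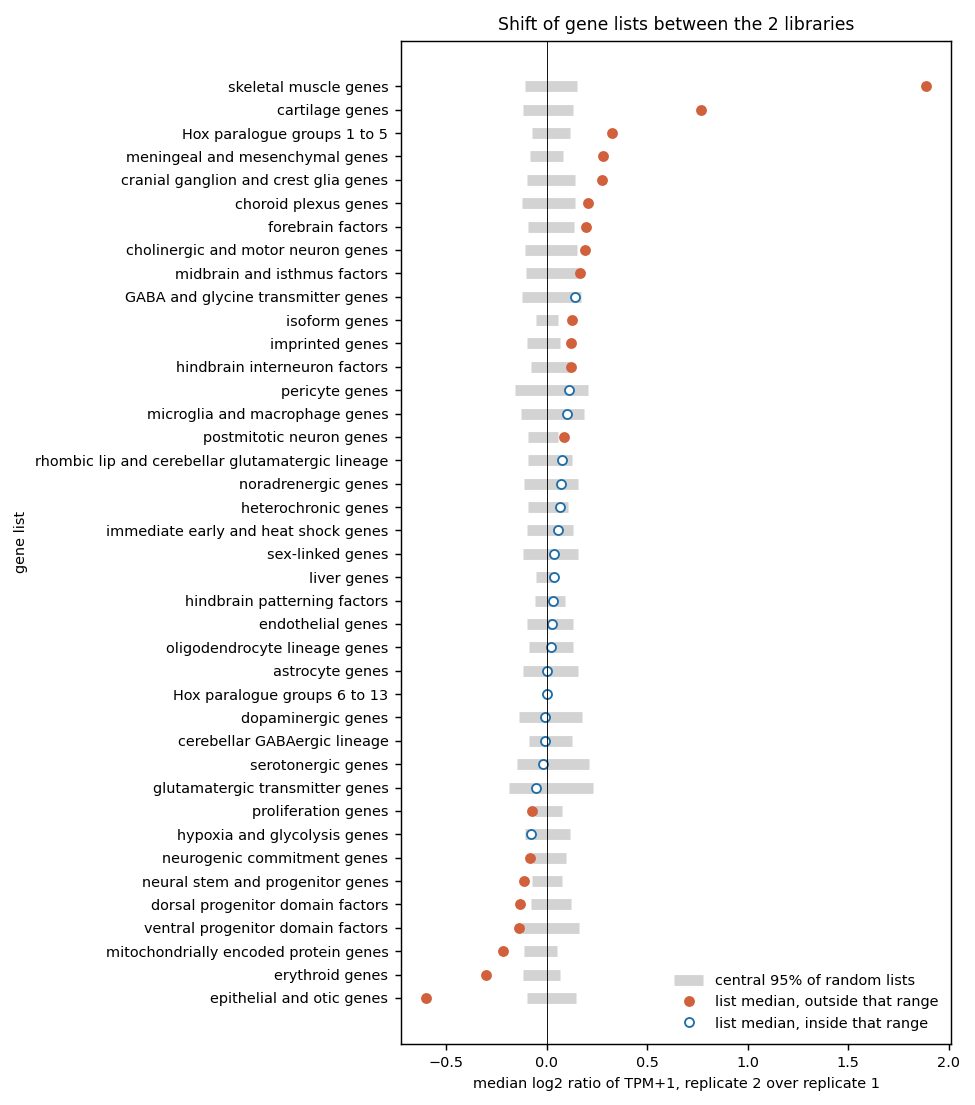
Median log2 ratio of TPM+1, replicate 2 over replicate 1 (horizontal axis), of each of the 40 gene lists, with the central 95% of random lists matched on size and level as grey bars, filled orange points outside that range and open blue points inside it. Skeletal muscle genes lie at 1.89 and epithelial and otic genes at -0.60.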

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

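Removing the trends with length and GC content, and recomputing TPM for the list shifts, were chosen after the data were seen. The Hox, midbrain and forebrain contrasts kept their direction under every alternative run. Of the list medians, 38 moved by more than their SD between libraries with FPKM, 27 with recomputed TPM and 7 with posterior mean TPM. With FPKM, 15 lists had a median of 10 or more in place of 25, the Hox difference was 3.19, hindbrain over midbrain 2.39 and hindbrain over forebrain 4.18. Within a library FPKM and recomputed TPM are each TPM times 1 constant, so their values show a change of unit and are no test of the lists or contrasts. With a pseudocount of 0.1 these differences were 6.91, 2.64 and 5.68. The forebrain contrast was 4.73 with TPM recomputed without spike-ins, mitochondrially encoded genes and other entries, and 4.43 with posterior mean TPM. Pearson's r was 0.949 with log2(TPM+0.1), 0.994 with no minimum level and 0.986 with FPKM. The edgeR exact test with the between-library dispersion added gave 301 calls in place of 3846. The dispersion widens the error allowed for, but the test changed too, and these changes were not run apart. DESeq2 size factors, total counts and no minimum count gave 3842, 3838 and 3572. As shares of expected counts, spike-ins were 3.88%, mitochondrially encoded genes 1.05%, globin genes 0.591% and the 10 highest genes 2.60%, lower than as shares of TPM because TPM divides by length. The dominant transcript was the same in 90.3% of genes at 1 TPM, 94.1% at 20 TPM and 99.9% where it led by 2-fold or more. That lead was taken from TPM summed over the same 2 libraries, so the 99.9% follows largely from the selection and is no test of agreement. Spike-in r was 0.998 at 5 or more counts. Where no cause is given, the cause was not tested. Detection was 16007 or 16016 genes in a single library, the spike-in share of TPM 8.39% to 10.9%, and the Hox difference 3.68 to 4.06. Leaving out a library gives no value for comparisons between the 2 libraries. The shifts of the skeletal muscle, cartilage, meningeal, epithelial and otic, Hox groups 1 to 5, cranial ganglion, erythroid and mitochondrial lists, the last not run with recomputed TPM, kept their direction and stayed outside the range of random lists in each alternative run. Recomputed TPM moves lists and random lists by nearly the same amount, so it is no test of these shifts. It moved that of proliferation genes from -0.07 to -0.04, and removing the trends to -0.11. Among the other lists the ventral progenitor list came inside the range with TMM-scaled CPM and with the trends removed, and hindbrain interneuron factors with CPM, while the GABA and glycine list moved out of it with CPM and the liver list with CPM and with a pseudocount of 0.1. Depth limits genes near 0.158 TPM.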

Other observations

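The tests of counting error, of surface ectoderm genes, of long erythroid genes and of spike-in length were chosen only after the result was seen, as were the removal of the length and GC trends and the margin of 1 standard error used to read each list against its range. The genes named here, apart from Dlx5 and Dbx1, were also chosen after their values were seen.

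Among transcripts of any type, several non-coding RNAs stood beside the highest protein-coding genes. The 7SL RNA genes Rn7s1 and Rn7s2, part of the signal recognition particle, were each listed at 9819 TPM in replicate 1 and 7087 TPM in replicate 2, so the division between the copies is uncertain. The nuclear RNA Malat1 was at 7327 ± 654 TPM (SD, n = 2). Gm42418 and Gm26917, both annotated as lincRNA, were at 3700 ± 619 and 3339 ± 71.4 TPM. The pseudogene Gm28437 was at 4452 ± 915 TPM. Whether the fragments given to Gm28437, Gm42418 and Gm26917 came from these loci or from similar sequences elsewhere was not tested. Gm22133, a microRNA gene with an effective length of 10 nt, was listed at 3856 ± 584 TPM, where so short a length raises the TPM of each count.

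Regional genes also differed between the pools in single cases. The forebrain factor Nkx2-1 was at 0.10 TPM in replicate 1 and 1.41 TPM in replicate 2 (adjusted p = 6.50e-08, edgeR exact test with dispersion added), and Dlx5 was at 8.61 and 15.2 TPM (adjusted p = 0.0201, same exact test). Dbx1, of a progenitor domain, was at 14.6 and 24.9 TPM, and Lbx1, of dorsal interneurons, at 8.84 and 15.2 TPM. In the transcript tables, the highest transcript was an intron-retaining form for Agrn (46.3% ± 2.26) and Gria2 (34.8% ± 1.34), and for 277 of 8395 genes, of which 8316 had a transcript type in M21.

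Skeletal muscle genes were higher in replicate 2, with summed TPM of the 8 genes at 62.9 and 249 in replicates 1 and 2. The tables argue against counting error, since 8 of 8 passed the exact test with dispersion added, and against transcript length or GC content as the whole cause, since the median log2 ratio was 1.91 after both trends were removed. A candidate explanation is more muscle tissue in the pool of replicate 2. A further list of 15 muscle genes, none held by another list, had a median log2 ratio of 0.77 against -0.13 to 0.19 for random lists, led by Cdh15 (1.79 to 5.71 TPM), and 6 of the 15 reached 1 TPM in both. The design has a single group, so beyond the tissue makeup of the pools no biological explanation was tested.

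The epithelial and otic list was lower in replicate 2. Removing the length and GC trends left the epithelial and otic list at -0.57, against these trends as the whole cause. Less epithelium of every kind is argued against by 10 surface ectoderm genes, 2 of them shared with that list, whose median log2 ratio was -0.0167 with Krt15 at 8.56 and 14.0 TPM. These genes do not cover every epithelium, and less of some other epithelium outside the inner ear was not tested. A candidate explanation is less inner ear tissue in the pool of replicate 2, as 12 further inner ear genes had a median log2 ratio of -0.34 against -0.12 to 0.17 for random lists, though 5 of the 12 reached 1 TPM in both libraries, their summed TPM was 0.834-fold, and Gjb2, the most abundant, was at 26.1 and 25.6 TPM. Beyond the tissue makeup of the pools, no biological explanation was tested.

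Erythroid genes were lower in replicate 2, as were short transcripts in general, with a median log2 ratio of -0.20 at effective lengths of 100 to 400 nt and 0.04 at 5000 nt and above. The erythroid shift went from -0.30 to -0.17 when the length and GC trends were removed and stayed below the range of random lists (-0.07 to 0.07), which argues against length as the whole cause while leaving it as a possible part. Fewer red blood cells could not be decided, since 10 long erythroid genes, 2 of them shared with the list, had a median of -0.15, below the bound of -0.13 by less than the standard error of 0.0995, and without that late margin the same value would have met the prediction for fewer red blood cells. A length effect that also acts on spike-ins stays open, as Spearman's rho of length with log2 ratio was 0.0646 across 47 spike-ins, with a bootstrap range of -0.230 to 0.346. Beyond the makeup of the pools, no biological explanation was tested.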
